A study of Caenorhabditis elegans with 2 samples.

How the data were processed

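Chromatin of whole L4 larvae of the eGFP-tagged jun-1 strain was immunoprecipitated and sequenced as 2 biological replicates, per the labels. The labels' extraction protocol gives no detail, and the aligner, the peak caller and their versions are not given in the sources used here. Per the labels, alignments and peaks were made on the ce10 and ce11 genome builds. The deposited peak lists are of 4 kinds per build, namely peak regions of replicate 1, of replicate 2, of both replicates jointly, and those of the joint list past a threshold on the irreproducible discovery rate. Per the deposited descriptions of the files, the regions were called from the alignments together with a control, whose own files were not used here. The replicate and joint lists hold background regions as well as peaks, since they served as input to the reproducibility step. Because every list is the outcome of calling against a control, regions of high background in the control would be lowered or missing, and neither read depth nor mappability can be recovered from the lists.

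The deposited signal per peak, in the seventh column of each list, is the peak caller's own value and its scale is not given in the sources used here. The deposited -log10 q-value per peak, in the ninth column, runs from 0.0176 to 3.01 in the joint ce11 list and was read but set no threshold. Signal was compared within a list and, between the replicate lists, by correlation, since its scale need not be shared between lists. The threshold list was the 899 strongest peaks of the joint ce11 list by signal, and 1068 of the joint ce10 list, so that taking the strongest peaks of the joint list gave the identical set. Main results used ce11, and ce10 lists entered only counts, shares and the replicate signal correlation, which need no annotation.

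Positions were set against the WBcel235 assembly, which is ce11, and Ensembl release 115 annotation. All ce11 peak ends lay within the chromosome lengths. A promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated transcript start of the 19973 protein-coding genes, and a gene was called bound when such a window held a summit. Replicates were compared by summits within 100 bp at matched list length. Shares in promoter windows and near small RNA genes (within 250 bp) were set against 1000 circular shifts of the summits within chromosomes, where the smallest two-sided p is 0.00200. Shares on X and in the central 50% of chromosomes were tested by exact binomial tests. Gene lists were tested by exact Fisher tests against all other protein-coding genes, and motifs by exact McNemar tests of windows of 101 bp at the summit and 500 bp to a randomly drawn side. P-values were two-sided and adjusted by Benjamini-Hochberg within each family of 35 lists, 10 motifs, 5 RNA classes or 6 chromosomes, with a threshold of 0.05. Intervals are exact binomial at 95% and cover counting error over peaks only. The labels name separate biosamples and do not say whether cultures were separate, so p-values over peaks describe these lists.

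The gene lists, motifs and main tests were fixed before the data were examined. The comparisons of promoter share between X and autosomes, of X among the 25 strongest peaks, of the central share per chromosome, of the replicate correlation by strength and of the GA repeat by strength were added afterwards. The rule for named genes was also fixed beforehand. It took the genes with a promoter window at the 25 strongest peaks or, failing that, the nearest gene, up to 4 bound members with the strongest peak of each list past the threshold, and 13 preset genes. Genes outside it were chosen after their values were seen. Alternatives changed the distance or overlap that counts as shared, the promoter and motif windows, the control sequence, the background, the threshold and the replicate used.

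The code was tested on simulated peak sets of 899 positions. At random positions, 1 of 1750 gene list tests, 2 of 500 motif tests and 0 of 50 RNA class tests were called. Promoter share was called in 0 of 20 random sets and the X share in 41 of 1000. Peaks planted at 30% of the members of lists with at least 20 genes were recovered in 50 of 50 runs. Motifs planted at 10% of summits were recovered in 9 of 10, with only the common CCAAT box missed. Smaller lists, lower planted shares of either, and random sets gathered at promoters were not simulated. Peaks planted at 20 small RNA genes were recovered in 5 of 5 classes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and BLAST+ 2.17.0 for genomic copies.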

Results

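Genomic sites recovered with tagged JUN-1, a nematode relative of the AP-1 transcription factor subunit JUN, were mapped by chromatin immunoprecipitation and sequencing in whole L4 larvae of Caenorhabditis elegans, the last larval stage before adulthood. The worms were of strain OP234, which carries a transgene of jun-1 tagged with eGFP on an unc-119 mutant background, and both sexes were pooled. The series held 1 group of 2 biological replicates, so no comparison between groups was possible, and the question the labels imply is where the tagged protein was found. The replicate lists held 19396 and 23742 peak regions on the ce11 genome for replicates 1 and 2, before any threshold on reproducibility. The list of regions found from both replicates together held 13085, of which 899 passed the authors' reproducibility threshold. Read depth was unknown, since the peak lists carry a signal per peak and no read counts. The signal is the authors' own value per peak, on a scale not given in the sources used here, and was used only to rank and describe peaks.

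The strongest sites lay at the same places in both replicates, led by intergenic sites on chromosome X and by the promoter of the ribosomal protein gene rpl-3 on chromosome III. The strongest reproducible site, at X from 11093980 to 11094361, had a signal of 294 in replicate 1 and 275 in replicate 2, and the rpl-3 site had 174 and 194. The site near xbp-1, which encodes a transcription factor of the endoplasmic reticulum stress response, had 79.4 and 75.5. Of the 899 strongest peaks of replicate 1, 513 had a summit within 100 bp of one among the 899 strongest of replicate 2, which is 57.1% (95% exact binomial interval 53.8 to 60.3). Over 1000 circular shifts of the positions within chromosomes, the mean was 0.186% and the highest value 0.779%. Of the reproducible peaks, 846 had a matching summit in both replicate lists. Across these peaks, which are not independent replicates, Spearman's rank correlation of the signals was 0.530 and Pearson's r on the log2 scale was 0.68. The rank correlation was 0.838 among the 25 strongest peaks and -0.528 among the weaker 407 matched peaks, a set selected on the joint signal of both replicates.

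**Figure D1:**
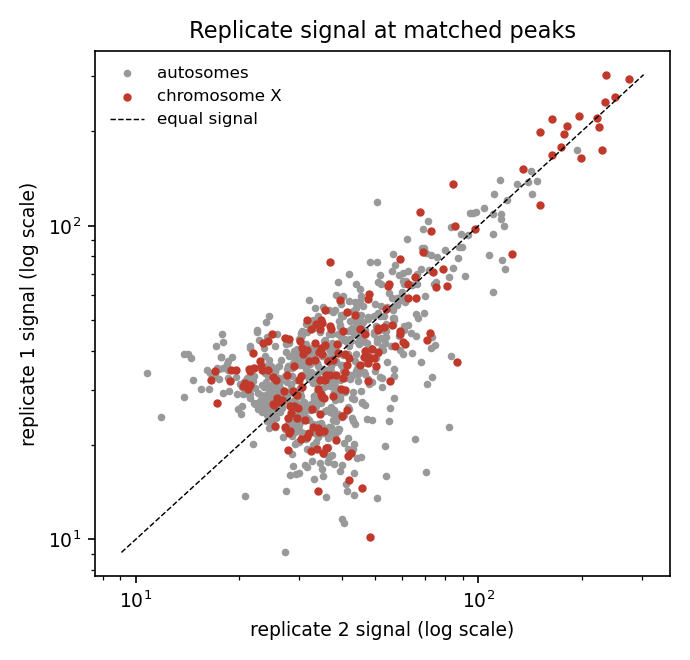
Signal of replicate 1 (vertical, log scale) against replicate 2 (horizontal, log scale) at the 846 reproducible peaks matched in both lists, with chromosome X in red, autosomes in grey and the dashed line at equal signal. The strongest sites, most of them on X, are high in both replicates, while weaker peaks scatter more widely.

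Chromosome X held most of the strongest sites, and most of these lay away from promoters. Of the 25 strongest reproducible peaks, 17 were on X, against 176 of the other 874 (68.0% and 20.1%). This contrast was noticed in these same peaks, so a test on them adds no support and no p-value is given. The peaks ranked 1 to 10 were all on X, with signals from 564 down to 379. The first was intergenic, with W02H3.3 as the gene of nearest transcript start, 3980 bp away. The peak ranked 2, at X from 6296373 to 6296776 with a signal of 537, was intronic, with its nearest start that of cest-16. The site ranked 15, at X from 8036220 to 8036649 with a signal of 336, was intergenic, and its nearest start was that of xol-1, the master switch gene of sex determination and dosage compensation.

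Only 3 of these 17 X sites fell in a promoter window, those of nspc-17 (rank 3, signal 499), fbxb-58 (rank 14, signal 348) and ins-39 (rank 18, signal 289), the last an insulin-related gene. The nearest starts to the others were those of K02D3.1, F19H6.5, ZK899.6, F55G7.5, C41A3.2, T27A8.7, F20B6.9, gtr-1, Y41G9A.17, F22H10.2 and F43E12.1. The median distance of the 17 summits from the nearest start was 2573 bp, against 524 bp for all other reproducible peaks. The 8 autosomal sites among the 25 strongest lay in promoter windows without exception. They were those of rpl-3 (signal 372), of tasp-1 and K01G5.10 (291), of egg-5 (280), of H41C03.3 (272), of cdc-48.1 (270), of rpl-15 and K11H12.8 (268), of the cytochrome oxidase subunit gene cox-5A (252) and of the histone gene his-37 (242). The peaks given for egg-5 and H41C03.3 also lie at the spliced leader RNA genes sls-2.4 and sls-2.1. Over the whole reproducible list, 193 peaks were on X, which is 21.5% (95% exact binomial interval 18.8 to 24.3) against 17.7% of the genome's length (two-sided exact binomial p = 0.00338). Chromosome III was denser still, with 11.5 peaks per Mb against 10.9 on X, and the joint list before the threshold had 20.7% of its regions on X. Without the 25 strongest peaks, a setting chosen after the data were seen, the share was 20.1% and no longer passed the threshold (exact binomial p = 0.0624). These tests treat peaks as independent and describe positions in these lists, not the spread between cultures.

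**Figure D2:**
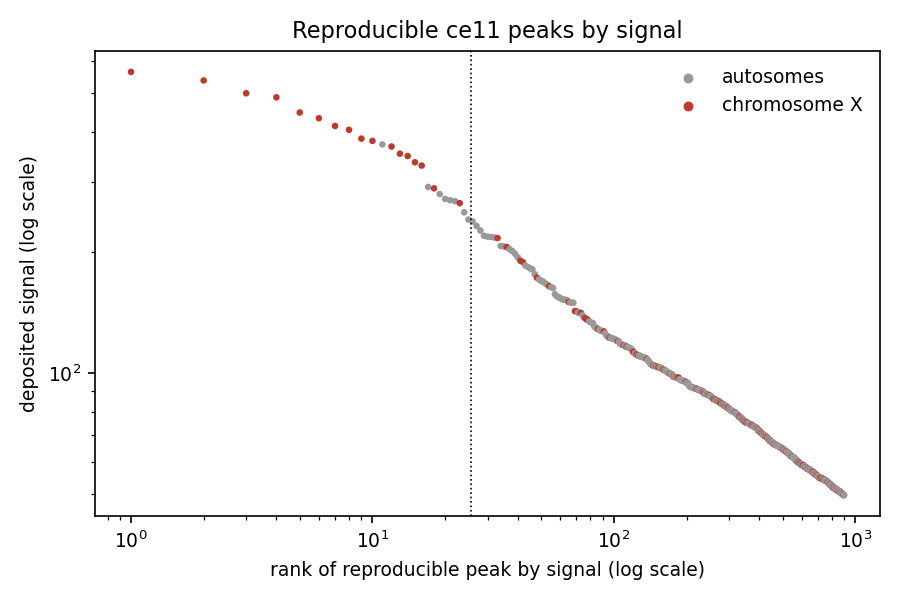
Deposited signal (vertical, log scale) of the 899 reproducible peaks against their rank (horizontal, log scale), with chromosome X in red, autosomes in grey and a dotted line after rank 25. The 17 X peaks left of the line include all of ranks 1 to 10.

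Reproducible summits gathered upstream of genes and were scarce inside coding sequence. Promoter windows, from 1000 bp upstream to 200 bp downstream of a transcript start, held 519 of the 899 summits (57.7%), as at rpl-3, cox-5A and cdc-48.1. The mean over 1000 circular shifts was 25.7% with an SD of 1.52 (two-sided permutation p = 0.00200, the smallest that these shifts can give). Intergenic sequence held 635 summits (70.6% against 37.1% shifted), introns 194 (21.6% against 33.7%) and coding exons 25 (2.78% against 24.4%). The raw share in promoter windows was lower on X than on the autosomes, a comparison chosen after the data were seen. It was 82 of 193 X summits (42.5%) and 437 of 706 autosomal ones (61.9%, two-sided exact Fisher p = 1.67e-06). Outside the 25 strongest peaks it was 79 of 176 (44.9%) and 429 of 698 (61.5%). The shifted mean is genome-wide, so the part of each chromosome that promoter windows cover was not allowed for. Whether X peaks favour promoters less than their chromosome would give was not tested.

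The middle of the chromosomes held slightly more peaks than the arms. Of all reproducible summits, 496 (55.2%, 95% exact binomial interval 51.9 to 58.5) lay in the central 50% of chromosome length (two-sided exact binomial p = 0.00214). Chromosome V, with 87 of 128 summits (68.0%, adjusted exact p = 0.000353), and chromosome I, with 88 of 142 (62.0%, adjusted exact p = 0.0163), passed the threshold singly, and the other 4 chromosomes did not. On X the share was 44.0% (adjusted exact p = 0.196). Among the stronger 449 peaks the genome-wide share was 51.2% and did not pass (exact binomial p = 0.637).

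Genes of ribosomal proteins, translation factors, the endoplasmic reticulum stress response and the respiratory chain carried reproducible promoter peaks far more often than all other protein-coding genes, and chemoreceptor genes far less often. The chemoreceptor contrast did not pass against the narrower background described below. Of 19973 protein-coding genes, 668 (3.34%) had a reproducible summit in a promoter window and were called bound. Whether these promoters, or the small RNA genes described below, are recovered with many proteins or through mislabelled libraries was not tested. Among 35 gene lists fixed before the data were examined, 12 passed an adjusted p of 0.05 in two-sided exact Fisher tests with Benjamini-Hochberg adjustment over the lists, 10 with more bound genes and 2 with fewer. At an unadjusted p under 0.05 there were 14.

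Ribosomal protein genes led by test, with 29 of 81 bound (35.8%, 95% exact binomial interval 25.4 to 47.2, adjusted exact p = 4.90e-21). Their strongest promoter peaks were at rpl-3 (signal 372), rpl-15 (268), rpl-35 (239) and rpl-20 (220). The peak at rpl-3 spans III from 3867456 to 3867685, with its summit 285 bp upstream of the start. Of the 29, 23 shared their peak with another gene's window, which the peak lists do not resolve. With each summit given only to its nearest start, 16 of 81 were bound (19.8%, adjusted exact p = 6.05e-09) and the odds ratio was 9.73, against 16.8 with all windows. Translation factors had 9 of 39 bound (23.1%, adjusted exact p = 2.49e-05), among them the initiation factor gene iff-2 (signal 227) and the elongation factor genes eef-1A.2 (129), eef-1G (106) and eef-1A.1 (90.4). The respiratory chain and ATP synthase list had 10 of 42 bound (23.8%, adjusted exact p = 6.40e-06), with cox-5A (252), cox-5B (92.3), atp-1 (91.5) and cox-6B (91.3). Vacuolar ATPase subunits had 4 of 20 (20%, adjusted exact p = 0.0125), which were vha-12 (97.9), vha-1 (85.5), vha-8 (74.4) and vha-13 (62.5).

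Genes of the endoplasmic reticulum stress response had the highest share, with 8 of 17 bound (47.1%, 95% exact binomial interval 23 to 72.2, adjusted exact p = 3.26e-07). These were led by xbp-1 (signal 154), the BiP chaperone gene hsp-3 (150), the protein disulphide isomerase gene pdi-3 (90.6) and enpl-1 (86.1). Heat shock proteins and chaperones had 12 of 60 bound (20%, adjusted exact p = 4.99e-06), led by hsp-3, the chaperonin gene cct-8 (150), hsp-1 (138) and hsp-90 (128). With each summit given only to its nearest start, that list fell to 6.67% and did not pass (adjusted exact p = 0.177). The bZIP factors, the family to which JUN-1 belongs, had 6 of 27 bound (22.2%, adjusted exact p = 0.000972), with cebp-1 (206), xbp-1, zip-2 (110) and zip-5 (65.9) the strongest. Autophagy and lysosome genes had 7 of 34 (20.6%, adjusted exact p = 0.000555), with the ubiquitin-like genes lgg-2 (140) and lgg-1 (77.99), epg-7 (103.96) and epg-8 (70.1). The bZIP and stress response lists share xbp-1 and atf-6 among their bound members, and the chaperone and stress response lists share hsp-3.

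Splicing factors had 5 of 30 bound (16.7%, adjusted exact p = 0.0103), led by snr-4 (signal 95.3), by rsp-1 and rsp-2, which share 1 peak (87.6), and by prp-40 (65.3). Cell cycle and replication genes had 6 of 58 (10.3%, adjusted exact p = 0.0370), led by cdc-48.1 (270), which encodes an ATPase of protein degradation, the PCNA gene pcn-1 (111), cdk-7 (87.01) and the Rb homologue lin-35 (79.5). Chemoreceptors had 6 of 1286 bound (0.467%, 95% exact binomial interval 0.171 to 1.01, adjusted exact p = 1.56e-11), led by srz-62 (97.8), srh-2 (78.8), srh-16 (73.3) and srh-269 (59.1). Antimicrobial and lectin genes had 2 of 353 (0.567%, adjusted exact p = 0.00337), clec-78 (96.0) and clec-126 (75.1). Among the members named, the peaks of eef-1A.1, snr-4, clec-126 and srh-269 also lay within 250 bp of a miRNA, snRNA or tRNA gene. Against a background of only those genes whose window holds a summit of the joint list, 7 of the 12 lists passed, and the bZIP, cell cycle, chemoreceptor, splicing and vacuolar ATPase lists did not (adjusted exact p from 0.118 to 0.393). The splicing and antimicrobial lists were also lost among the stronger 449 peaks (adjusted exact p = 0.0516 and 0.270). The splicing odds ratio there was 6.13, against 5.82 in the main test, and the antimicrobial one 0.308 against 0.162. Also lost was the cell cycle list without the 25 strongest peaks (8.62%, adjusted exact p = 0.0977, odds ratio 2.78 against 3.36).

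**Figure D3:**
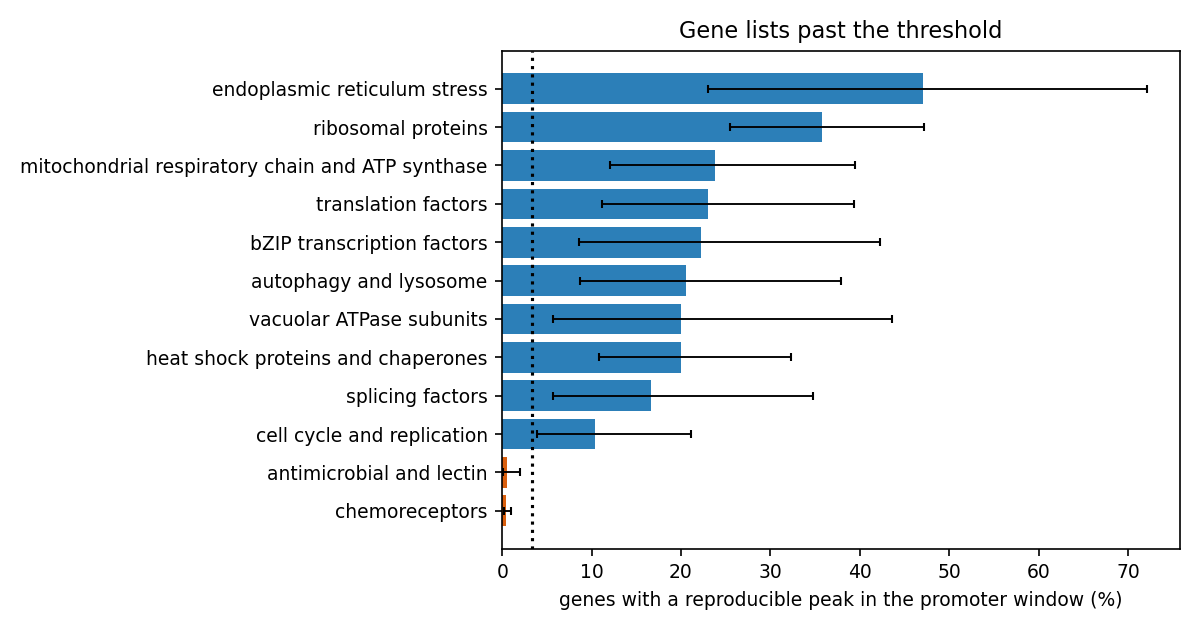
Share of each gene list's members with a reproducible peak in the promoter window, in percent, for the 12 lists past the threshold. Bars in blue are above other genes and those in orange below, whiskers are 95% exact binomial intervals, and the dotted line marks the 3.34% of all protein-coding genes.

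The other 23 lists did not pass. Those with bound members were proteasome subunits (3 of 33), aminoacyl-tRNA synthetases (1 of 32), histones (1 of 72), cuticle collagens (3 of 175), nuclear hormone receptors (11 of 274), homeobox factors (2 of 90), oxidative stress and glutathione (2 of 73), cytochrome P450 and UDP-glucuronosyltransferases (2 of 141), the JNK and p38 cascades (1 of 19, the phosphatase gene vhp-1), vulval induction (1 of 23), germline (2 of 56), neuropeptides and insulins (1 of 140), muscle (2 of 39), intestine (3 of 40), F-box and MATH domain genes (6 of 395), lipid metabolism (1 of 72), and actin and tubulin (3 of 18). No member had a reproducible promoter peak among molting and hedgehog-related genes (0 of 78), basement membrane and anchor cell invasion genes (0 of 23), ovulation and inositol trisphosphate signalling genes (0 of 14), neuronal genes (0 of 27), major sperm proteins (0 of 43) or vitellogenins (0 of 6). Of these 23 lists, 4 passed under some alternative. F-box and MATH domain genes passed, with fewer bound, with windows from 500 bp and from 2000 bp upstream (adjusted exact p = 0.0408 and 0.0363). Actin and tubulin genes passed, with more bound, with windows from 2000 bp (0.0218) and without peaks near small RNA genes (0.0450). With no member bound, cuticle collagens passed without replicate 1 (adjusted exact p = 0.0230), and neuropeptides and insulins without the 25 strongest peaks (0.0459).

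Of 13 genes chosen beforehand, 2 had a reproducible promoter peak, the CREB homologue crh-1 (rank 569, signal 60.6) and the intestinal GATA factor gene elt-2 (rank 441, signal 68.0). The jun-1 gene had none in its promoter windows, and 1 reproducible summit lay within its span, at II 9131703 with a signal of 90.5. That summit was near the downstream end of jun-1, which spans II from 9113157 to 9132231 on the plus strand. It fell in an annotated 5' untranslated region, and which transcript this region belongs to was not resolved. A summit in an intron of him-4 (X 9743616, signal 85.8) lay beside tRNA genes, and skn-1 also held an intronic summit (IV 5657263, signal 77.1). For fos-1, which encodes the partner of JUN-1 in AP-1, a promoter region appeared only in the joint list before the threshold (rank 1249, signal 43.03). The same held for atf-7 (rank 1940, signal 35.5), kgb-1 (rank 3222, signal 28.5) and the promoter of skn-1 (rank 4473, signal 25.04). No joint-list summit lay in the promoter windows of jun-1, him-4, unc-119, plc-1, zmp-1, cdh-3 or jnk-1.

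Summits lay near tRNA, snoRNA, snRNA and miRNA genes more often than shifted positions did, although most such genes had no peak. A peak lay at 9.48% of tRNA, 9.30% of snRNA, 15.6% of snoRNA and 2.30% of miRNA genes. Of the reproducible summits, 50 lay within 250 bp of a tRNA gene, 53 of a snoRNA gene, 18 of a snRNA gene and 6 of a miRNA gene. The strongest were at the spliced leader RNA genes sls-2.4 (signal 280), sls-2.1 (272) and sls-2.2 (233), whose products are joined to messenger RNAs by trans-splicing. The sls-2.2 peak had a matching summit in replicate 2 (signal 130) and none in replicate 1. Of the 18 SL2 RNA genes, 6 had a peak. These shares were 5.56%, 5.90%, 2.00% and 0.667% of the summits, against shifted means of 0.352%, 0.216%, 0.0699% and 0.148%. The adjusted permutation p was 0.00333 for tRNA, snRNA and snoRNA genes and 0.0150 for miRNA genes. No summit lay near any of the 20 rRNA genes (adjusted permutation p = 1). In all, 125 peaks (13.9%) lay near such a gene. Of these, 49 also lay in a promoter window of a protein-coding gene, a position that the shifts do not keep.

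A repeat of GA was the most enriched of the 10 sequence motifs at the summits, and the AP-1 recognition site was rare. The sequence GAGAGA lay within 50 bp of 266 of the 899 summits (29.6%, 95% exact binomial interval 26.6 to 32.7) and in 61 control windows 500 bp away (6.79%, two-sided exact McNemar test, adjusted p = 1.71e-35). Dinucleotide-shuffled summit windows held it in 14.6%. The E-box CACGTG was in 42 summit windows (4.67%) and 17 control windows (1.89%, adjusted exact p = 0.00508), and in 4.12% of dinucleotide-shuffled summit windows (adjusted exact p = 0.779). Its call also ended under 3 other alternatives that kept more sites at summits than in control windows. These were leaving out replicate 2 (3.23% against 1.67%, adjusted exact p = 0.145), windows of 25 bp either side (2.00% against 0.890%, 0.151) and the stronger 449 peaks (4.45% against 2.00%, 0.174). The AP-1 site TGASTCA was in 24 summit windows (2.67%, interval 1.72 to 3.95) and 12 control windows (1.33%), which did not pass (exact p = 0.0576, adjusted 0.165). That call changed with the draw of the control side, left or right of each summit. With the left side alone 0.667% of control windows held the site (adjusted exact p = 0.00477), with the right side alone 1.11% (adjusted exact p = 0.0430). Of 100 other draws 73 passed, with a median control share of 0.890%, all choices made after the data were seen. Among alternatives fixed beforehand, the site passed within 100 bp of the summit (5.01% against 2.00%, adjusted exact p = 0.00153) and with controls at 1000 bp (0.667%, adjusted exact p = 0.00178). It also passed without replicate 1 (adjusted exact p = 0.0267) but not without replicate 2 (0.0534). It did not pass against shuffled summit windows, which have no side (1.67%, adjusted exact p = 0.326). Nor did it within 25 bp of the summit (1.11% against 0.890%, adjusted exact p = 0.893) or among the stronger 449 peaks (1.78% against 1.56%, adjusted exact p = 1). The other 7 motifs did not pass against the control windows, namely the CRE, SKN-1, GATA, DAF-16, C/EBP, CCAAT and heat shock sequences. The GATA site passed in opposite directions under 2 alternatives. It was in 9.90% of summit windows against 3.78% of shuffled ones (adjusted exact p = 4.69e-07), and in 6.24% against 12.2% of control windows among the stronger 449 peaks (adjusted exact p = 0.0159). The C/EBP site passed without replicate 1 (adjusted exact p = 0.0130), without the 25 strongest peaks (0.0195) and with the right side alone (0.0260), where the heat shock sequence also passed (0.0430). Over the 100 other draws of the control side, the CCAAT box passed in 18, with fewer at summits, the C/EBP site in 5 and the heat shock sequence in 2.

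The AP-1 site was not more frequent at stronger peaks. It was in 8 of the stronger 449 peaks (1.78%) and 16 of the weaker 449 (3.56%), an odds ratio of 0.491 that did not pass (two-sided exact Fisher p = 0.146). Without replicate 1 the odds ratio was 1.31 (exact p = 0.674). The GA repeat was in 141 (31.4%) and 125 (27.8%) of the same sets (exact p = 0.273).

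**Figure D4:**
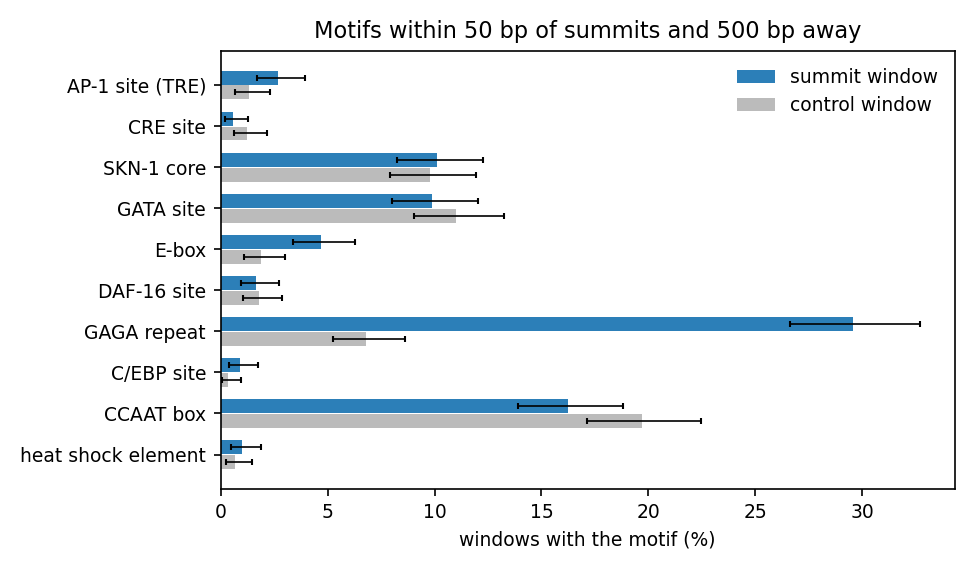
Share of windows, in percent, that hold each of 10 motifs within 50 bp of the reproducible summits (blue) and in control windows 500 bp away (grey), with 95% exact binomial intervals as whiskers. The GAGA repeat stands at 29.6% against 6.79%, and the AP-1 site at 2.67% against 1.33%.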

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

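Leaving out the 25 strongest peaks, leaving out peaks near small RNA genes, and the left-only and right-only controls were chosen after seeing the data. Taking the strongest peaks of the joint list changed nothing by construction, and no ce10 test of the X or central share was run because ce10 chromosome lengths were not used here. No result past its threshold reversed. The promoter share passed under 7 of 7 alternatives (46.6% to 69.7%), the 4 RNA classes under 6 of 6 and the GA repeat under 12 of 12. Each of these counts includes the strongest peaks of the joint list, which are the identical set and add no support. Replicate overlap moved with its definition, to 47.3% for summits within 50 bp, 63.6% for 1 bp of interval overlap, 64.6% for the strongest N/2 peaks and 48.8% for 2N. The rank correlation of replicate signals became 0.594 at 50 bp. The stricter list held 449 peaks by construction, and its central share of 51.2% did not pass. The X share fell to 20.1% without the 25 strongest peaks. The joint-list background left 7 gene lists, with fewer genes tested. The count of motifs past the threshold was 1 at 25 bp, 4 without the 25 strongest peaks, 5 with the right-hand control and 1 to 4 over the sets that left out a replicate. The E-box did not pass at 25 bp (2.00%), against shuffled windows (4.67%), in the stricter list (4.45%) or without replicate 2 (3.23%, against 4.89% without replicate 1). The AP-1 site passed at 100 bp (5.01%), with controls at 1000 bp or on one side (2.67% each), without the 25 strongest peaks (2.75%), away from small RNA genes (2.97%) and without replicate 1, but not without replicate 2 (2.56% in both). Those 2 sets had equal counts (controls 0.890%, exact p = 0.0107), so only the adjustment over the other motifs differed (0.0267 and 0.0534). It also did not pass at 25 bp (1.11%), against shuffled windows or in the stricter list (1.78%). Some of these changes also redrew the control side. The odds ratio of the AP-1 site by strength ran from 0.764 to 1.31 with a replicate left out, a change of direction without replicate 1. Apart from the redrawn controls and the constructions named, the cause was not tested. Unknown read depth limits any statement on sites absent from the lists.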

Other observations

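The tests of gene families, of the X recruitment element and of the 8-base word were chosen after the patterns were seen. Outside the fixed lists, grouping genes by the stem of their name gave 419 families of at least 5 genes, of which 6 passed in exact Fisher tests with Benjamini-Hochberg adjustment. Of these, 2 were not covered by a fixed list. In the sec family, which mixes genes of protein translocation and secretion, 6 of 19 were bound (31.6%, adjusted exact p = 0.00268). Its strongest peaks were at the translocon genes sec-61.G (signal 156) and sec-61.B (131), and sec-61.A (70.4) shared its peak with rps-18. The peak of sec-15 (73.0) also lay within 250 bp of a tRNA gene. Family tests were not repeated under other settings. In the mdt family of Mediator subunits, 5 of 20 were bound (25%, adjusted exact p = 0.0353), namely mdt-26 (72.9), mdt-1.2 (56.3), mdt-6 (54.3), mdt-19 (54.1) and mdt-22 (49.9).

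Peaks at tRNA genes were mostly on X, with 32 of 50 (64%), where 276 of the 612 annotated tRNA genes (45.1%) lie. Peaks at snoRNA genes were mostly on autosomes, with 2 of 53 on X, where 33 of 346 snoRNA genes lie. The difference was not tested.

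Most of the X-linked sites that head the signal ranking carried a shared sequence. The consensus TCGCGCAGGGAG, known from sites that recruit the dosage compensation complex to X, was matched at 10 or more of 12 positions within 100 bp of the summit in 13 of the 17 X peaks among the 25 strongest (76.5%, 95% exact binomial interval 50.1 to 93.2). It was so matched in 6 of the other 176 X peaks (3.41%, exact Fisher p = 1.04e-12), in none of the 8 autosomal peaks among the 25 strongest and in 7 of the other 698 autosomal peaks (1.00%). Of the control windows of the 17 strongest X peaks, 2 (11.8%) held it. The X peaks ranked 4, 5, 6 and 23 fell short, with best matches at 7, 7, 9 and 7 positions. The full consensus stood in the peak of rank 1, at X from 11094123 to 11094134 on the minus strand, and in the intronic peak of rank 13, at X from 2997121 to 2997132. Across the genome, 32 sites on X matched at 11 or more positions and 17 of them (53.1%) lay within 100 bp of a reproducible summit, against 0 of 37 on the autosomes. Of these 17 sites, 14 lay at the strongest peaks already counted, and sites can share a peak, so this is no separate evidence.

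None of the 17 windows held the element after a single dinucleotide shuffle of each (exact McNemar p = 0.000244). With 13 windows that hold it, this p is the smallest the test can give. So long a sequence is seldom remade by shuffling. The shuffle therefore shows only that base composition alone rarely gives the element, and it does not say why these peaks carry it. Copies of most of the window elsewhere in the assembly were not the source of the pattern. Of the 17 summit windows, 0 had another genomic copy at 90% identity over 80% of the window (interval up to 19.5%). Such copies were also rare at the other X peaks (6.25%). Shorter repeats and copies missing from the assembly were not examined. A candidate explanation is that chromatin at dosage compensation recruitment sites was recovered in this experiment. Whether the tagged JUN-1 itself binds there, whether such sites are recovered with many proteins, or whether the libraries were mixed or mislabelled was not tested. The lowest signals among the 17 peaks were 117 in replicate 1 and 135 in replicate 2, where the list medians were 10.9 and 10.1. These values argue against a fault in a single library, and they do not bear on a fault shared by both. The design has 1 group, so no biological difference between groups was tested.

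The GA repeat at summits was not accounted for by composition alone or by position near genes alone. Dinucleotide-shuffled summit windows held it in 14.6%, against 29.6% of the windows themselves and 6.79% of control windows, so composition could account for part of the excess. Windows at the same offsets from starts of genes without a reproducible peak held it in 6.92%, against 27.2% of the 519 summits in promoters (exact Fisher p = 2.05e-39). Those transcript starts were drawn at random, so a gene with several starts could enter more than once, and the test counts its windows as independent. They were not matched to the bound genes by class or activity, so only position was compared. A factor that binds GA repeats may share these sites, and this was not tested.

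The 8-base word with the greatest excess at summits over control windows on chromosomes I, II and III was AGACGCAG, or CTGCGTCT on the other strand. It was in 49 of 434 summit windows there and in 3 control windows. Chance among the 18976 words seen could give such an excess, so the word was tested on chromosomes IV, V and X. It was in 50 of 465 summit windows there (10.8%) and in 3 control windows (0.645%, exact McNemar p = 5.52e-12). The word was less frequent on X, in 12 summit windows (6.22%), than on all autosomes, in 87 (12.3%). That autosomal share includes the chromosomes on which the word was chosen. Which protein binds the word was not tested.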
